A study of Homo sapiens with 10 samples.

How the data were processed

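RNA from 10 cultures of the lung adenocarcinoma lines PC9, PC9M and H358 was sequenced by the authors. Each culture formed a group of its own: DMSO and GNF5 in all 3 lines, and scrambled and ABL1/ABL2 shRNAs in PC9 and PC9M. Transduction used 8 µg/mL polybrene. Reads were aligned with TopHat and compared with Cuffdiff on hg18, per the labels, with versions and annotation not stated. The authors' tables give FPKM for both libraries of each pair, scaled within that table. They also hold deposited p-values and q-values of Cuffdiff's test of 1 library against 1. The 5 tables were normalised separately, so only ratios within a table were tested, and levels set across tables are named as such. In the H358 table the name of the treated sample leaves open whether a further condition shared its run.

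The tables were joined by gene symbol. In each of them 28 entries whose symbol had turned into a date were left out, as was EEF1A1, which has no estimate in the table for PC9 with GNF5, and 23234 genes were in all 5. Symbols were matched to a reference annotation to mark 18612 as protein-coding. Listed loci start at 0-based positions, so 1 was added to each start. No library columns were identical. Read depth is unknown. Steps in the low FPKM values put the depth of the treated over the control library at 1.01 in PC9, 1.02 in PC9M and 1.19 in H358 for GNF5, and at 1.16 in PC9 and 1.05 in PC9M for the shRNAs. No counting intervals can be given for FPKM.

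Within a pair the log2 ratio of FPKM plus 1 was taken. Genes at least 2-fold apart were counted among those with an FPKM of at least 1 in either library, with no test, because there is 1 library per group. Of 38 gene lists fixed before the data were examined, those with at least 5 measured members were described by their median ratio and its percentile among 10000 random lists of equal size, matched on expression in 20 bins. The medians lay outside the central 95% for 16, 20 and 15 of 34 lists with GNF5 in PC9, PC9M and H358, and for 13 and 16 with the shRNAs in PC9 and PC9M. Random lists were drawn gene by gene, so they do not keep the correlation of related genes. Between control libraries, scrambled over DMSO, across tables and centred, many lists also lay outside. In PC9 and in PC9M they were at least as many as with GNF5 or with the shRNAs. Mitotic genes were at 1.76 in PC9, for example, and interferon genes at 1.41 in PC9M. A median outside the range is thus no sign of a treatment effect by itself. A fold was not given against a library listed at 0.

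Across lines the 5 ratios were fitted in limma 3.58.1 (R 4.3.3) with perturbation as the factor, a trended prior and 3 residual degrees of freedom, for 13885 genes with at least 1 FPKM in 2 or more libraries. The 4 contrasts were GNF5, shRNA, their average and their difference, each adjusted by Benjamini-Hochberg at 0.05. In some fits, genes listed at 0 in several libraries had no spread between ratios, and limma moved their variance off 0. The p-values measure the spread between single libraries of different lines, and PC9 and PC9M may not be independent lines, to judge by their names. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. The fit was tested on simulated data with 200 changed genes. At a log2 change of 1 it recovered 67% of them for GNF5, 0% for the shRNAs and 85% for the average, with 15, 2 and 13 false calls beside them, and at a log2 change of 2 it recovered 94.5%, 92.5% and 97.5%, with 11, 12 and 16 false calls. In each of these 6 cases false calls made up more than the 5% of calls that the adjustment aims at. The simulated noise was independent between genes and drawn with each gene's moderated variance. A changed gene was shifted equally in all 5 ratios. The shares recovered describe that setting and need not hold for the real ratios. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

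Named genes followed a rule fixed before the data were examined. It takes ABL1 and ABL2, then the 10 highest and 10 lowest genes of each pair with at least 5 FPKM in the higher library and at least a 2-fold difference. Across lines it takes called genes or, where there are none, the 10 in each direction with the largest mean among genes past 0.58 in every line, and up to 4 members of each list described. Under that rule the lists of single pairs held almost only small nucleolar and micro RNAs listed at 0 in 1 library. The restriction to protein-coding genes was therefore added after the data were seen, for single pairs, for the genes past 0.58 in every line and for PC9M against PC9. GNF5 had 1 called gene, so its list of genes past 0.58 was also added then. Genes in the plot of levels by library were chosen by hand after their values were seen. Alternatives fixed beforehand were other pseudocounts, other minimum levels, centring of the ratios, an untrended prior, leaving out each comparison, a replicate block by line in PC9 and PC9M, and fits to a single perturbation. Protein-coding genes alone, rank correlations, the control libraries against each other and 2 alternatives for the lists were added later. Some genes that this rule selects are not reported here. A test of olfactory receptor genes by chromosome, set beforehand, was dropped because an increase on every chromosome follows from the increase in their total, and a test on other silent genes took its place.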

Results

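Transcript levels were measured by RNA sequencing in 3 human lung adenocarcinoma cell lines, PC9, PC9M and H358. The labels describe PC9M as spreading more to bone and brain, and its name ties it to PC9. The ABL kinases ABL1 and ABL2, non-receptor tyrosine kinases that regulate the cytoskeleton and growth signalling, were inactivated by the allosteric inhibitor GNF5 or by shRNAs against both genes. GNF5 was given for 72 h in all 3 lines, with DMSO as the control. The labels write the dose as 10 mM for PC9 and H358 and 20 mM for PC9M, a unit that could not be checked. Scrambled shRNA served as the control for the ABL1/ABL2 shRNAs in PC9 and PC9M. Each of the 10 groups held 1 library, so there are no replicates within a group, and values within a pair of libraries carry no error. The authors' tables list FPKM, normalised within each of the 5 pairs separately. The number of reads per library is unknown, because the tables hold no counts. Between 11287 and 12793 genes had an FPKM of at least 1 in a library. All values below are log2 ratios of treated over control library after adding 1 to each FPKM, unless another unit is named, and positions are on the hg18 genome.

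The level of the targeted genes was compared first. ABL1, at chromosome 9 from 132579089 to 132752883, was listed at 24.9 FPKM in the PC9 scrambled library and at 3.97 FPKM with the shRNAs, a log2 ratio of -2.38. In PC9M the pair was 10.5 and 3.56 FPKM, a ratio of -1.33. ABL2, at chromosome 1 from 177335085 to 177465442, had ratios of -1.63 in PC9 and -0.63 in PC9M with the shRNAs. The authors' deposited table gives q = 6.03e-07 for ABL1 and q = 0.0482 for ABL2 in PC9, and q = 1.11e-06 and q = 0.503 in PC9M. Those values compare 1 library with 1 library. With GNF5, which acts on the protein, ABL1 transcript ratios lay between -0.19 and -0.01, and ABL2 ratios between 0.10 and 0.65.

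**Figure D1:**
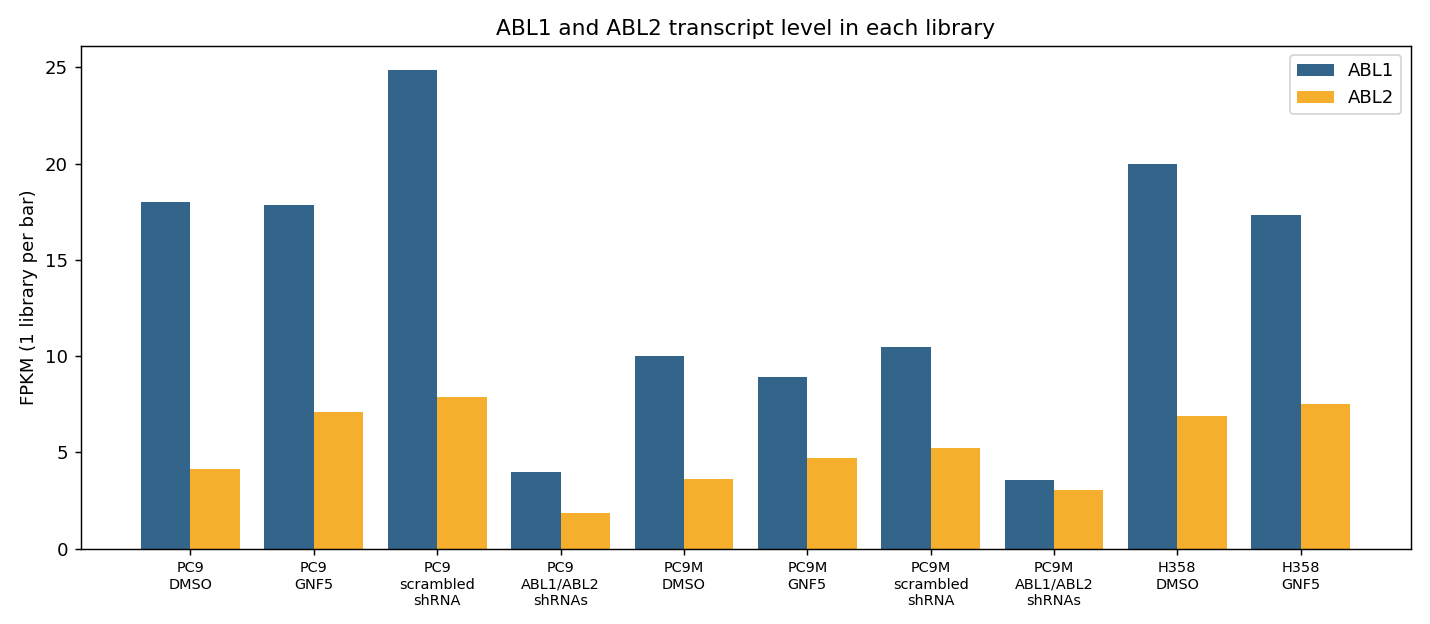
Bars show the FPKM of ABL1 and ABL2 in each of the 10 libraries, 1 library per bar and no error. ABL1 stands at 3.97 and 3.56 FPKM in the shRNA libraries of PC9 and PC9M, against 24.9 and 10.5 in their scrambled controls.

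GNF5 in PC9 was examined for the transcripts that differ when ABL kinase activity is blocked. The most prominent group was cholesterol synthesis: 22 of the 24 measured genes were higher in the GNF5 library, 16 of them at least 2-fold, with a list median of 1.53. Among them were HMGCS1, the enzyme that makes HMG-CoA, at 24.0 FPKM with DMSO and 199 with GNF5, the sterol sensor INSIG1 at 2.96, squalene epoxidase SQLE at 2.86 and MSMO1 at 2.56. Of the fatty acid genes 7 of 11 were higher, SCD at 1.45 and FASN at 1.38 by at least 2-fold, and the glycolytic and hypoxia genes ALDOC and NDRG1 stood at 3.36 and 1.60. Lower in the GNF5 library were amino acid response genes under ATF4, with CHAC1, which degrades glutathione, at -2.67 and the cystine transporter SLC7A11 at -2.57.

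Other high entries in PC9 with GNF5 were NEURL3 at 3.65, the polyamine enzyme SAT1 at 3.12, RHOV at 2.58 and the sodium channel subunit SCNN1G at 2.47. Low entries were DMBT1 at -3.18, the immediate early genes FOS and FOSB at -2.71 and -2.64, CCDC64B at -2.62, KRCC1 at -2.59, CPVL at -2.59 and the EGFR ligand HBEGF at -2.53. Antigen presentation genes were all on the higher side, 12 of 12, with TAP1 at 1.81 and HLA-B at 1.72, and the NF-kB genes TNFAIP3, BIRC3 and RELB stood at 2.39, 2.27 and 2.06. Mesenchymal genes had a median of 0.40, with the transcription factor SNAI2 at 2.14, while integrins such as ITGA2 at -1.44 and ITGB3 at -1.29 were lower. NRF2 targets had a median of -0.65, 18 of 21 being lower.

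In all, 621 genes were at least 2-fold higher and 820 at least 2-fold lower in PC9 with GNF5, of 12004 with an FPKM of at least 1 in either library. The PC9 controls stand apart from each other: after centring, the scrambled library differed from the DMSO library at least 2-fold for 2136 genes, against 1380 for GNF5 over DMSO, the former set across separately normalised tables. Between those control libraries the ATF4 list differed by a median of -1.49, cholesterol synthesis by 0.48 and NRF2 targets by -0.42 with 16 of 21 lower, scrambled over DMSO, each in the direction seen with GNF5.

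GNF5 in PC9M gave another picture. Genes of DNA replication were lower in the GNF5 library without exception, 37 of 37, with a median of -1.09. They included the flap endonuclease FEN1 at -1.50, UHRF1 at -1.49, the cyclin CCNE2 at -1.48 and MCM10 at -1.40. Mitotic genes were lower in 33 of 33 cases, with a median of -0.80, KIF20A at -1.24 and CDC20 at -1.23. The ATF4 list lay on the other side, with a median of 0.85 and 21 of 24 genes higher: asparagine synthetase ASNS stood at 2.55, CHAC1 at 2.45, DDIT3 at 1.92 and PCK2 at 1.80.

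Of the stress genes in PC9M with GNF5, NUPR1 stood at 2.59, the secreted factor GDF15 at 2.30 and HERPUD1, a part of ER-associated degradation, at 1.95. All 19 measured ER chaperone and unfolded protein response genes were higher, with the chaperone HSPA5 at 1.39. Complement factor CFB at 2.29, SPRR1A at 2.19, the defensin DEFB1 at 2.09 and C15orf48 at 1.89 completed the highest 10. The lowest were ALPP at -2.17, FAM111B at -1.71, NPTX1 at -1.62, WNT9A at -1.60, the splicing factor HNRNPM at -1.52, ANKRD2 at -1.50, and MYBL2 and EXO1, both at -1.49, together with FEN1 and UHRF1. Heat shock genes had a median of -0.78, with HSP90AA1 at -1.18. Cholesterol synthesis had a median of -0.56, with ACAT2 at -1.18, opposite to PC9.

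A total of 195 genes were at least 2-fold higher and 224 at least 2-fold lower in PC9M with GNF5, of 12370. Short RNAs made up 42.5% of them. The scrambled and DMSO controls of PC9M differed at least 2-fold for 351 genes, across tables and after centring, against 420 for GNF5 over DMSO. Between those controls, scrambled over DMSO, the ATF4 list differed by a median of 0.51, ER chaperones by 0.24 with 18 of 19 higher, antigen presentation by 0.37 and cholesterol synthesis by -0.42 with 24 of 25 lower, each in the direction seen with GNF5. The same held for fatty acid synthesis, at -0.68 with 11 of 11 lower, and for NRF2 targets, at -0.63 with 20 of 21 lower, which is further than the -0.37 with GNF5.

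GNF5 in H358 was marked by lower levels of interferon response and DNA replication genes. Of 34 measured interferon response genes 33 were lower, 11 of them at least 2-fold, with a median of -0.81. IFI27 stood at -1.82, IFI6 at -1.75, the antiviral GTPase MX1 at -1.73 and IFI44L at -1.49. Replication genes were lower in 36 of 36 cases, with a median of -0.97, GINS2 at -1.83, MCM5 at -1.59, E2F1 at -1.53 and MCM3 at -1.38. The squamous regulator TP63 stood at -2.41, keratin KRT4 at -3.49, and the YAP/TAZ targets CTGF and CYR61 at -1.55 and -1.27.

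Further low entries in H358 with GNF5 were GPR116 at -2.25, LBH at -2.22, FGFBP1 at -1.97, CDCA7 at -1.91, CX3CL1 at -1.86 and CDH6 at -1.78. BMP-responsive ID3 and ID2 stood at -1.39 and -1.14, and the lung lineage factor NKX2-1 at -0.98. Highest was CYP1A1, a target of the aryl hydrocarbon receptor, at 2.82. It was followed by the ER retention receptor KDELR3 at 1.59, the GTPase ARF4 at 1.51, GFPT1 at 1.35, COG6 and GOLGA3, both at 1.34, MKNK2 at 1.33, RPL21 at 1.30, TMED7-TICAM2 at 1.27 and the signal recognition particle receptor SRPR at 1.26.

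In H358 145 genes were at least 2-fold higher and 311 at least 2-fold lower, of 12951, and 50.4% of them were short RNAs. Among protein-coding genes 28 were higher and 174 lower. With the ratios of protein-coding genes centred on their own median, 77 were higher and 83 lower. The median ratio over all genes counted was -0.192 in H358, and between -0.097 and -0.009 in the other comparisons. Once the ratios were centred on that median, the share of higher genes among those at least 2-fold apart moved from 31.8% to 49.6% in H358, from 43.1% to 54.7% in PC9 and from 46.5% to 56.7% in PC9M, all for GNF5.

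Across the 3 lines, the average of the GNF5 ratios was tested with limma, in a fit of all 5 ratios. Antigen presentation genes were higher on average, with a median of 0.48 and HLA-B at 1.12 (SE 0.283), and their medians in the single lines were 0.79 in PC9, 0.35 in PC9M and 0.13 in H358. The DNA replication average, with a list median of -0.65 and UHRF1 at -1.11 (SE 0.216), came from PC9M and H358, since in PC9 17 of 33 genes were higher. The NF-kB average, with a median of 0.54 and RELB, a subunit of NF-kB, at 1.41 (SE 0.302), came from PC9 and PC9M, since in H358 5 of 13 genes were higher and the median was -0.15. ER chaperones had a median of 0.20, with HERPUD1 at 1.08 (SE 0.277), and in H358 a median of 0.01.

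No protein-coding gene passed the limma test for GNF5 at a Benjamini-Hochberg adjusted p of 0.05. The single gene of 13885 that did was MIR149, with an adjusted p of 0.0240 and a listed locus on chromosome 2 from 241023788 to 241056168. It stood at 32.2, 44.4 and 17.1 FPKM in the DMSO libraries of PC9, PC9M and H358 and was listed at 0 in their GNF5 libraries. In the scrambled and shRNA libraries of PC9 and PC9M it was listed at 0 as well, so its shRNA ratios are 0 in both lines and narrow the spread used in the test. With the GNF5 ratios alone limma called 0 genes. An unadjusted p under 0.05 was reached by 2359 genes, and by 1898 with the ratios centred on their median. The MIR149 call was lost whichever comparison was left out. Other short RNAs were called then, 5 without PC9 GNF5 and 2 without PC9M GNF5, and the count was 0 without H358 GNF5, without PC9 shRNA or without PC9M shRNA.

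Protein-coding genes with a ratio of at least 0.58 in size in each of the 3 lines missed the test but were more numerous than independent lines would give. There were 25 higher, against 0.914 expected, and 65 lower, against 14.0 expected. The higher ones were led by RELB, GDF15 at 1.39, the deacetylase HDAC9 at 1.34, ATG9B at 1.20, the ubiquitin ligase subunit FBXO32 at 1.18, C1orf38 at 1.15, the lysosomal glycoprotein CD68 at 1.14, SELM at 1.14, CYP1B1 at 1.12 and RND1 at 1.12. The lower ones were led by KRT4 at -1.99, NCOA5 at -1.35, TNS4 at -1.34, the splicing factors SFPQ at -1.22 and HNRNPM at -1.20, PRMT6 at -1.20, C9orf116 at -1.14, HMGB3 at -1.09, SLC19A1 at -1.06 and TUBB4B at -1.05. Their limma adjusted p lay between 0.242 and 0.261. The ratios were not centred, and their medians were -0.097, -0.062 and -0.192 in PC9, PC9M and H358. Protein-coding genes at least 2-fold apart in opposite directions also exceeded expectation for PC9 with PC9M (20 against 8.7) and PC9 with H358 (8 against 4.5). For PC9M with H358 there were 0 against 1.2. In the same direction, at least 2-fold, there were 18 higher (3.0 expected) and 9 lower (5.9 expected) for PC9 with PC9M. For PC9 with H358 there were 2 higher (0.7) and 16 lower (5.7), and for PC9M with H358 2 higher (0.2) and 25 lower (1.2). In the pairs with PC9 both kinds of count thus exceeded expectation. The excess of genes past 0.58 alone therefore does not show a shared response.

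camera with a preset correlation called 11 of the 36 tested lists for GNF5, each at a Benjamini-Hochberg adjusted p under the threshold of 0.05. DNA replication had adjusted p = 1.52e-07, antigen presentation 1.06e-07, NF-kB genes 7.44e-06 and ER chaperones 2.41e-05, and these calls held whichever comparison was left out. For each of the 11 lists the adjusted p = 0.910 with an estimated correlation, and fry called none. Without PC9M GNF5, 6 lists were called. Adjusted over the list alone, 14 of 37 replication genes, 5 of 13 antigen presentation genes, 4 of 17 NF-kB genes and 0 of 19 ER chaperones passed, against 0 over all genes.

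The other 7 calls hung on single comparisons. Mitosis (lower, adjusted p = 0.0172) was lost without PC9M GNF5, where its direction turned, and without H358 GNF5. Cholesterol synthesis (higher, adjusted p = 0.00293) turned lower without PC9 GNF5. Targets of ATF4 (higher, adjusted p = 0.00481) and heat shock genes (lower, adjusted p = 0.0474) were lost without PC9M GNF5 or without H358 GNF5. NRF2 targets (lower, adjusted p = 0.00681) and core histones (higher, adjusted p = 0.0172) were lost without PC9 GNF5 or without PC9M GNF5. Hypoxia genes (higher, adjusted p = 0.0474) had a median of -0.03 and a mean of 0.11, which differ in sign, and the call was lost in 4 of the 5 fits that left out a comparison, being kept without PC9M GNF5. Adjusted over the list alone, 2 of 21 NRF2 targets and 1 of 25 ATF4 genes passed, and none in the other 5 lists. With an estimated correlation the value was, as above, adjusted p = 0.910 for each.

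The ABL1/ABL2 shRNAs in PC9 were examined for the transcripts that differ when both kinases are depleted. Keratinisation genes had the lowest list median, -0.75, with 18 of 20 lower and 8 at least 2-fold lower. Keratins KRT6B, KRT6A and KRT14 stood at -2.66, -2.46 and -1.83. KRT6A, KRT6B and KRT6C, at -2.77, are close paralogs that can share reads, so their separate values are uncertain. Ribosomal protein genes were slightly higher, 40 of 41, with a median of 0.39, and cholesterol synthesis genes were higher in 23 of 24 cases, with TM7SF2 at 1.82.

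Mitotic genes in PC9 with the shRNAs had a median of -0.34, with CDK1 at -1.08, and all 24 measured ATF4 genes were lower, with CHAC1 at -1.51. EGFR ligands and receptors had a median of -0.51, with EREG at -0.79 and EGFR at -0.73. Among the highest genes were PRSS2 at 2.19, the epithelial factor SPDEF at 2.09, TM7SF2, WNT6 at 1.68, argininosuccinate synthase ASS1 at 1.60, AGR2 at 1.46, the AXL ligand GAS6 at 1.39, FAM20C at 1.39 and C1orf53 at 1.25. Besides the keratins and ABL1, the lowest were KRT3 at -2.33, the disulfide isomerase PDIA4 at -2.25, the syndecan SDC4 at -2.22, SKP1 at -2.20, TFF1 at -2.16 and HDGF at -2.12.

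Of 11861 genes, 143 were at least 2-fold higher and 228 at least 2-fold lower in PC9 with the shRNAs, short RNAs making up 40.4%. With the ratios centred on their median the counts were 175 and 186. The authors' deposited table marks 101 of the joined genes as significant here, 81 of them lower.

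In PC9M the shRNAs went with higher interferon response genes. Of 33 measured members 32 were higher, 17 at least 2-fold, with a median of 1.03. OAS2 stood at 2.26, ISG15 at 1.90, IFIT1 at 1.90 and MX1 at 1.76. Keratinisation genes were lower, 15 of 16, with a median of -0.82, S100A8 at -2.76, KRT6A at -1.79, SPRR1A at -1.58 and SPRR1B at -1.53. NF-kB genes had a median of -0.42, with IL6 at -1.49 and TNFAIP3 at -1.16, and the EGFR ligands AREG, EREG and HBEGF stood at -1.24, -1.05 and -0.92.

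Among the highest in PC9M with the shRNAs were IFITM1 at 2.23, MX2 at 1.75, the TGF-beta receptor TGFBR1 at 1.64, IFI6 at 1.63 and IFI44 at 1.53. H3F3A was listed at 0 in the scrambled library and at 9.30 FPKM with the shRNAs. The lowest were CHAC1 at -1.82, S100A9 at -1.50, the siderophore-binding LCN2 at -1.49 and PRKAR1B at -1.45, with ABL1 as the last of the 10. Oxidative phosphorylation genes were higher in 29 of 30 cases, with COX7B at 0.62, and mitotic genes in 32 of 33, with CENPA at 0.89.

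Of 12126 genes, 123 were at least 2-fold higher and 98 at least 2-fold lower in PC9M with the shRNAs, and 66.1% of these were short RNAs. Between the PC9M controls, across tables and centred, the interferon list differed by a median of 1.41, keratinisation by 0.99 and the ATF4 list by 0.51, each higher in the scrambled than in the DMSO library. CHAC1 was listed at 0.91 FPKM with DMSO, 7.23 with scrambled and 1.33 with the ABL1/ABL2 shRNAs.

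**Figure D2:**
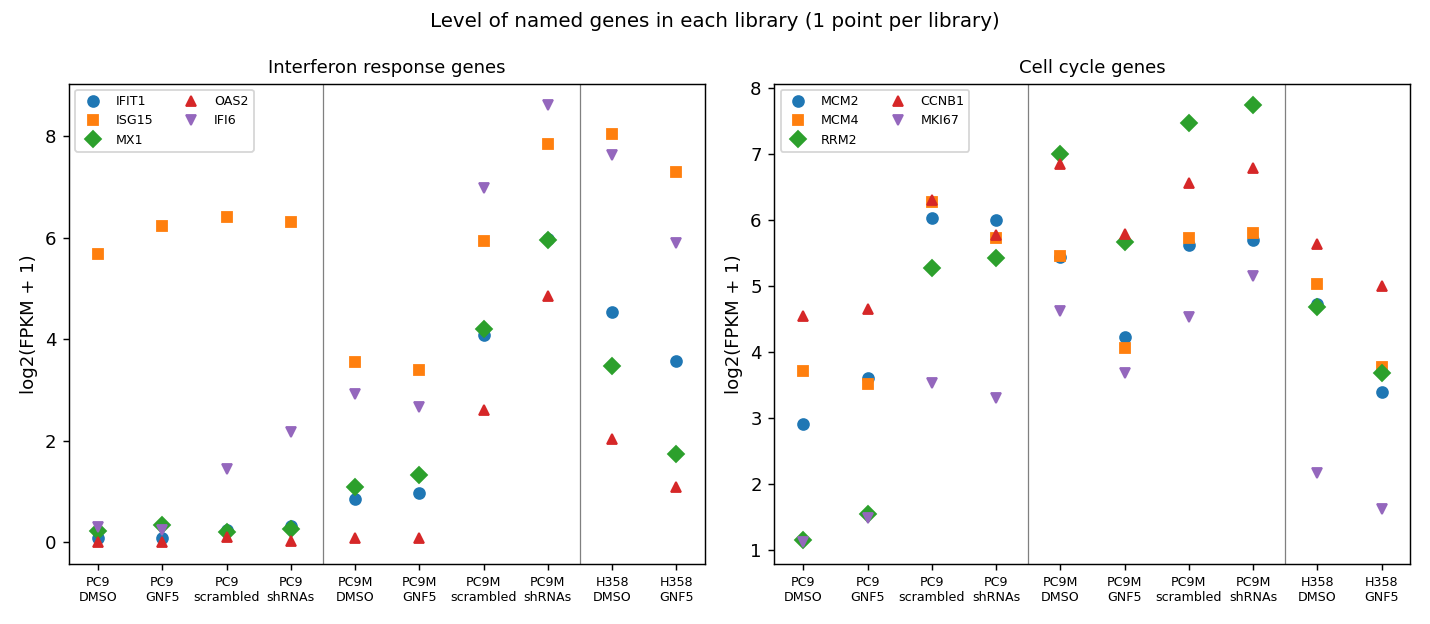
Points give log2 of FPKM plus 1 for named interferon and cell cycle genes in each of the 10 libraries, 1 point per library, with levels from separately normalised tables. IFI6 stands at 6.52 FPKM in PC9M DMSO, 125 in PC9M scrambled and 389 with the shRNAs, and RRM2 at 1.22 FPKM in PC9 DMSO and 37.7 in PC9 scrambled.

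**Figure D3:**
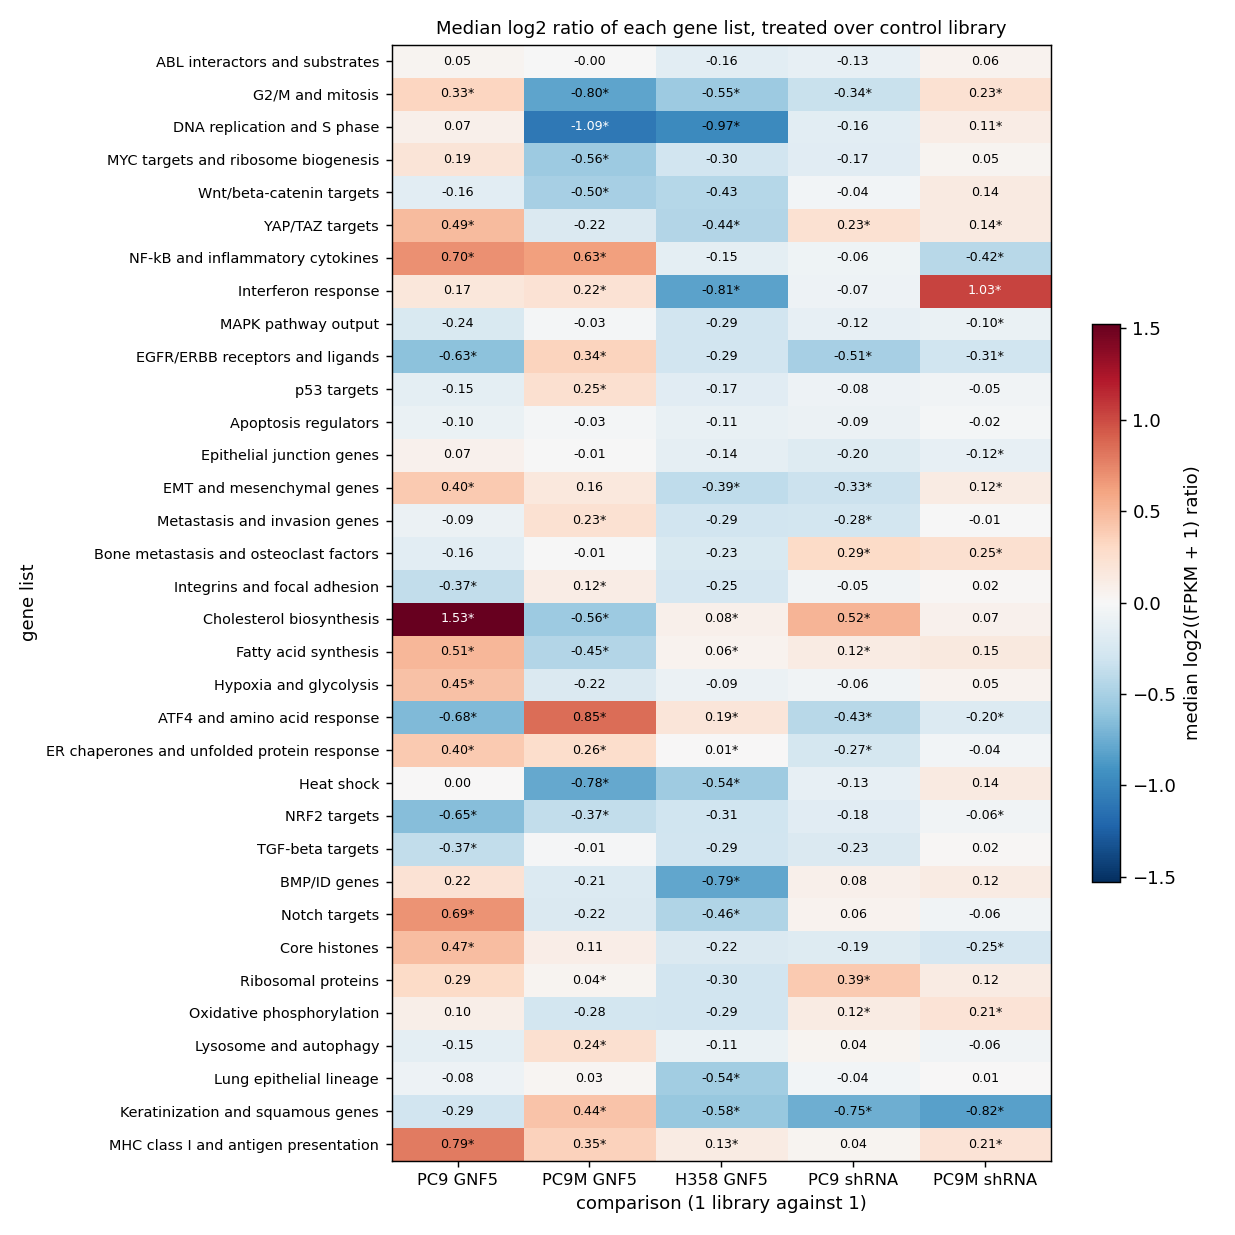
Colours and numbers give the median log2 ratio of each of 34 gene lists (vertical axis) in each of the 5 comparisons (horizontal axis), and an asterisk marks a median outside the central 95% of 10000 random lists matched on expression. Cholesterol synthesis reaches 1.53 in PC9 with GNF5 and -0.56 in PC9M, and keratinisation is at -0.75 and -0.82 with the shRNAs. Between control libraries at least as many list medians lay outside the central 95% in PC9 and in PC9M, so an asterisk alone does not mark a treatment effect.

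Across both lines the shRNAs went with lower keratinisation genes, with a median of -0.73, and slightly higher ribosomal protein and oxidative phosphorylation genes, with medians of 0.25 and 0.16. The ribosomal median lay outside the range of random lists matched on expression only in PC9, at 0.39. In PC9M it was 0.12, inside the range of 0.045 to 0.16. The scrambled libraries themselves stood on the other side of DMSO for most of these gene groups, across tables and centred. Keratinisation was higher in them by 0.44 in PC9 and 0.99 in PC9M. Ribosomal proteins differed by -0.74 in PC9 and -0.25 in PC9M, with 41 of 41 and 40 of 41 lower, and oxidative phosphorylation by -0.34 in PC9M, with 30 of 30 lower, and by 0.14 in PC9. KRT6A averaged -2.13 (SE 0.239), ABL1 -1.86 (SE 0.258), PDIA4 -1.79 (SE 0.253), SDC4 -1.69 (SE 0.268) and PRKAR1B, a regulatory subunit of protein kinase A, -1.57 (SE 0.159). Higher in both lines were TGFBR1 at 1.42 (SE 0.227), DCBLD2 at 1.20, WNT6 at 1.19, IFI6 at 1.17, ASAP1 at 1.16 (SE 0.132), C20orf4 at 1.14, ZCCHC2 at 1.02, ACAP2 at 1.02 and SLC36A1 at 0.98. Also lower were KRT6B, S100A8, KRT6C, CHAC1 and SKP1, between -1.98 and -1.51.

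None of these passed, with a limma adjusted p of 0.545 for ABL1 and 0.351 for PRKAR1B. An unadjusted limma p under 0.05 was reached by 595 of 13885 genes, a smaller share than the 0.05 that unchanged genes would give. After adjustment limma called 0 genes for the shRNAs. The count was 4 without PC9 GNF5, 2 without PC9 shRNA and 5 without PC9M shRNA, all of them short RNAs. Protein-coding genes with a ratio of at least 0.58 in size in both lines numbered 56 higher, against 4.69 expected of independent lines, and 88 lower, against 9.51.

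camera with a preset correlation called 7 lists for the shRNAs. Calls for ribosomal proteins (adjusted p = 2.39e-12), oxidative phosphorylation (adjusted p = 2.36e-06) and keratinisation (adjusted p = 2.39e-12) held whichever comparison was left out. That check is weak. Without a GNF5 comparison the mean shRNA ratios stay the same, and without an shRNA comparison only 1 shRNA ratio remains. Interferon response (higher, adjusted p = 5.65e-09), ATF4 targets (lower, adjusted p = 0.00861) and antigen presentation (higher, adjusted p = 0.00861) were lost without PC9M shRNA, with values of 0.731, 0.0510 and 0.299. Cholesterol synthesis (higher, adjusted p = 0.00127) was lost without PC9 shRNA, at 0.453, although 11 lists were called there. Each of the 7 had adjusted p = 0.967 with an estimated correlation, and fry called none. Adjusted over the list alone, 10 of 20 keratinisation genes passed and none in the other 6 lists, against 0 over all genes.

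GNF5 and the shRNAs were then set against each other. On average over both, limma called 0 genes, with 1336 at an unadjusted p under 0.05, and PRKAR1B had the lowest p of the protein-coding genes, averaging -1.16 (SE 0.102, adjusted p = 0.168) and being lower in 5 of 5 comparisons. The test of the difference also called 0, with 1137 at an unadjusted p under 0.05. Its lowest p among protein-coding genes was that of SMAD6, an inhibitor of BMP signalling, with shRNA minus GNF5 at 1.42 (SE 0.191, adjusted p = 0.543). Without PC9 GNF5 the counts were 4 on average and 5 for the difference, without PC9M GNF5 2 and 1, and without PC9 shRNA 1 and 1. No protein-coding gene had a ratio of at least 0.58 in size and in the same direction in all 5 comparisons.

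For the average of both, camera called 8 lists. Antigen presentation (adjusted p = 2.03e-09) and ribosomal proteins (adjusted p = 1.52e-09) were higher, and keratinisation (adjusted p = 5.18e-05) and NRF2 targets (adjusted p = 0.00322) lower, whichever comparison was left out. For GNF5, camera did not call ribosomal proteins or keratinisation (adjusted p = 0.0719 and 0.463), and their medians were 0.03 and -0.06. With the shRNAs those medians were 0.25 and -0.73. NRF2 targets were not called for the shRNAs (camera adjusted p = 0.362), with a median of -0.095. Replication genes (lower, adjusted p = 7.80e-05) were lost without PC9M GNF5, at 0.0802. NF-kB genes (higher, adjusted p = 0.0126) were lost without PC9M GNF5 or without PC9 shRNA. Interferon response (higher, adjusted p = 2.19e-04) was lost without PC9M shRNA, at 0.984, and cholesterol synthesis (higher, adjusted p = 8.00e-06) without PC9 GNF5, at 0.0590. Each had adjusted p = 0.889 with an estimated correlation, and fry called none. Adjusted over the list alone, 2 of 20 keratinisation genes and 1 of 21 NRF2 targets passed, and none in the other 6 lists.

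The 10 relations between comparisons were computed across genes, which are not independent replicates. The closest was between the shRNA comparisons of PC9 and PC9M, with Pearson r = 0.351 and Spearman rho = 0.445 over 11146 genes, and r = 0.499 over protein-coding genes. Of protein-coding genes, 13 were at least 2-fold lower in both, against 0.4 expected, and 5 were higher in both, against 0.1. GNF5 in PC9M and in H358 had r = 0.209 and rho = 0.332, with r = 0.383 over protein-coding genes, of which 25 were at least 2-fold lower in both, against 1.2 expected. Within PC9M, GNF5 and the shRNAs had r = -0.201 and rho = -0.275, with r = -0.299 over protein-coding genes. Of those, 9 were at least 2-fold apart in opposite directions, against 0.5 expected, with 0 higher in both and 0 lower in both. The remaining 7 had r between -0.042 and 0.128, and between -0.153 and 0.219 over protein-coding genes.

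In the authors' deposited tables, 23 genes are marked significant for the shRNAs in both PC9 and PC9M, all 23 in the same direction. In PC9M, 11 are marked for both GNF5 and the shRNAs, 1 of them in the same direction. These marks come from tests of 1 library against 1 library, so they do not measure differences between cultures.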

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

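Of the tests in this part, those of a depth difference, reads outside transcripts, a response in every line, a knockdown response in both lines, the dose and the scaling were chosen only after the result was seen, as were the swaps of treated and control. A list was singled out where its medians in 2 lines under the same perturbation lay outside the range of random lists on opposite sides, and the olfactory receptor genes because they lie outside the main comparisons. With 1 library per group none of these differences between lines was tested.

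With GNF5, 11 lists had medians on opposite sides. Cholesterol synthesis differed by 2.09 between PC9 (1.53) and PC9M (-0.56). Targets of ATF4 differed by 1.53 between PC9M (0.85) and PC9 (-0.68). Notch targets differed by 1.15 between PC9 (0.69) and H358 (-0.46). Mitotic genes differed by 1.13 between PC9 (0.33) and PC9M (-0.80). Interferon genes differed by 1.03 between PC9M (0.22) and H358 (-0.81). Keratinisation differed by 1.02 between PC9M (0.44) and H358 (-0.58). EGFR ligands and receptors differed by 0.97 between PC9M (0.34) and PC9 (-0.63). Fatty acid synthesis differed by 0.96 between PC9 (0.51) and PC9M (-0.45). YAP/TAZ targets differed by 0.93 between PC9 (0.49) and H358 (-0.44). Mesenchymal genes differed by 0.80 between PC9 (0.40) and H358 (-0.39), and integrins by 0.49 between PC9M (0.12) and PC9 (-0.37). The control libraries of PC9 and PC9M, scrambled over DMSO, across tables and centred, already differed in the same direction for some lists. ATF4 targets were at 0.51 in PC9M and -1.49 in PC9, and cholesterol synthesis at -0.42 and 0.48. EGFR ligands and receptors were at 0.30 and -0.52, and mitotic genes at -0.09 and 1.76. Fatty acid synthesis was at -0.68 in PC9M and -0.40 in PC9 between them, and integrins at 0.13 and 0.21. In PC9 both were opposite in sign to the GNF5 median. H358 has no scrambled library. Interferon genes and keratinisation in PC9M were at 1.41 and 0.99 between controls, above their GNF5 medians. In PC9, Notch targets were at -0.565, YAP/TAZ targets at 0.20 and mesenchymal genes at 0.24. Whether GNF5 or a difference between cultures accounts for the GNF5 differences cannot be told from 1 library per group. With the shRNAs, mitotic genes differed by 0.57 between PC9M (0.23) and PC9 (-0.34), and mesenchymal genes by 0.45 between PC9M (0.12) and PC9 (-0.33).

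Cell cycle genes were lower with GNF5 in PC9M and H358, in 70 of 70 and 69 of 69 measured genes, and not in PC9, where 39 of 65 were higher. Scaling of the H358 table is argued against by its centred median of -0.45. A PC9 DMSO library that was already low stays open: across tables and centred, its cell cycle genes lay -1.93 from the PC9 scrambled library in the median, 70 of 70 being lower, while the same difference in PC9M was -0.07. The PC9 pair may therefore say little about a response of these genes. Dose stays open for the same reason, although PC9 and H358 carry 1 dose in the labels and their medians lie 0.85 apart, and so does a difference between the lines.

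Interferon genes were higher in PC9M with the shRNAs, with a median of 1.03. A control below the DMSO level is argued against, since the PC9M scrambled library lay 1.41 above DMSO in the median, across tables and centred. The labels name no transduction for the DMSO culture. Whether the scrambled library was low for a transduced culture therefore stays open. A shared response to the knockdown of equal size in both lines is argued against only for the 16 members measured in both, with medians of -0.07 in PC9 and 0.76 in PC9M, although IFI6 was at 0.72 in PC9, while it stays open for 17 members under the minimum in PC9. Whether a few members carry the list stayed undecided, as 69.7% of members were above 0.58 (23 of 33) and the bounds set beforehand called for less than 50% or at least 75%, although 32 of 33 were above 0. A response to viral transduction or to 1 of the shRNAs may also raise these genes, and it was not tested.

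Olfactory receptor genes, which encode odorant sensors, were listed above 0 for 200 of 373 genes in H358 with GNF5 (median 0.0148 FPKM), against 53 in its DMSO library and 20 to 33 in the libraries of PC9 and PC9M. The ratio of 3.77 is above the depth ratio of 1.19, which argues against depth alone. Its exact 95% interval, 2.78 to 5.21, treats detected genes as independent counts, though the same genes were scored in both libraries. It does not measure the spread between cultures, and nor do the other intervals here. Reads that do not come from transcripts, such as genomic DNA, may be the source: of 1264 other protein-coding genes listed at 0 in all 8 libraries of PC9 and PC9M, 710 were listed above 0 in H358 with GNF5 and 287 with DMSO, a ratio of 2.47 (2.15 to 2.85). Low transcription of many silent genes would look alike. A response to GNF5 in every line was not decided, with ratios of 1.07 in PC9 (0.61 to 1.89) and 1.45 in PC9M (0.79 to 2.70).

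Swapping treated and control within pairs gave 16 splits of the 5 comparisons, too few for a share under 0.05. For GNF5 the real count was 1, 6 splits gave as many or more, the real one among them, and the highest other gave 3. Some of the 6 swapped only shRNA pairs and left every GNF5 ratio as it was, with counts of 2, 2 and 1. They are no other grouping for GNF5. The rest swapped PC9M GNF5 and 1 shRNA pair, with a count of 3 each. For the average and for the difference the real count was 0, which any split meets whatever the data. All 16 did, with a highest other of 1 in each, so the swaps cannot decide anything there.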

How the results depend on the processing

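Counts over protein-coding genes alone and rank correlations were chosen only after the data were seen, and the other alternatives before. No correlation changed sign, and the cause of the moves was not tested unless the alternative tests fewer genes. Genes at least 2-fold apart numbered 2302, 713, 762 and 583 at a pseudocount of 0.1 in PC9, PC9M and H358 with GNF5 and in PC9 with the shRNAs. At a pseudocount of 5 they numbered 628, 222, 257 and 190, and 140 in PC9M with the shRNAs. Protein-coding genes alone gave 219 and 202 in PC9M and H358 with GNF5, and 194 and 69 in PC9 and PC9M with the shRNAs. limma's counts for GNF5 were 3 at a pseudocount of 0.1, 2 with centred ratios, 2 at a minimum of 5 FPKM, and 0 at a pseudocount of 5, with no minimum, with protein-coding genes alone, with the replicate block by line in PC9 and PC9M, and with the GNF5 ratios alone. For the shRNAs they were 1 at a pseudocount of 0.1 and 1 with centred ratios, and at a pseudocount of 0.1 they were 2 for the average and 2 for the difference. The replicate block by line gave 0 for the shRNAs, the average and the difference as well. Leaving out 1 comparison at a time gave 0 to 5 genes for GNF5, 0 to 5 for the shRNAs, 0 to 4 for the average and 0 to 5 for the difference, and 6 to 11, 5 to 11 and 8 to 12 lists for GNF5, the shRNAs and the average. Where this leaves a perturbation with 1 ratio, that ratio is assumed to vary like the others. Leaving out a comparison of 1 perturbation does not change the mean ratios of the other, only the spread used to test them. With an estimated correlation and with fry, 0 lists were called in each of the 3 contrasts. Over protein-coding genes, r was 0.383 for GNF5 in PC9M and H358, 0.499 for the shRNAs in PC9 and PC9M, and -0.153 for H358 GNF5 and PC9M shRNA. The rank correlation for GNF5 in PC9M and H358 was 0.332. Genes at least 4-fold apart between PC9M and PC9 numbered 1411 at a pseudocount of 0.1. Of the values of single named genes under other pseudocounts and centring, 229 stayed within the spread between the PC9M controls and 95 moved, 66 of them at a pseudocount of 5. Read depth, which sets the precision of low FPKM, is unknown.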

Other observations

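The genes named in this part for single lines were restricted to protein-coding ones, a choice made after the data were seen, and the differences in level were not tested. PC9M and PC9 differed widely in their control libraries, although their levels come from separately normalised tables. Of 13150 genes, 328 were at least 4-fold higher and 392 at least 4-fold lower in PC9M, both with DMSO and with scrambled shRNA. BASP1, a membrane-bound growth protein, was listed at 68.6 FPKM in PC9M DMSO and 0.02 in PC9 DMSO. Fibronectin FN1 was listed at 401 and 5.17 FPKM, the matrix protein gene CTGF at 73.2 and 0.01, and the chemokine gene IL8 at 49.4 and 0.61. OLR1, MT1F, TFPI, DIO2, OXCT1 and KYNU were the other members of the highest 10. On the lower side, the squamous keratin KRT13 was listed at 0.27 FPKM in PC9M DMSO and 880 in PC9 DMSO, the cancer-testis gene MAGEA4 at 0.01 and 182, the peptidase gene ANPEP at 0.24 and 153, and DHRS2 at 3.26 and 506. KRT16, VCX3A, SLC1A6, GPR116, NOVA2 and TFF1 completed the lowest 10.

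Across libraries the interferon genes stood at very different levels. IFI6 was listed at 0.23 FPKM in PC9 DMSO, 6.52 in PC9M DMSO, 125 in PC9M scrambled, 389 in PC9M with the shRNAs and 197 in H358 DMSO. Cell cycle genes differed between the PC9 controls: RRM2, a subunit of ribonucleotide reductase, was listed at 1.22 FPKM with DMSO and 37.7 with scrambled shRNA, and MCM2, a part of the replicative helicase, at 6.53 and 64.6. In PC9M the pairs were 127 and 177 for RRM2 and 42.3 and 48.1 for MCM2. Markers of other cell types were low or shared with epithelial lines. The leukocyte genes PTPRC and CD3E were listed at 0.10 FPKM or less in every library, and CD68 at 4.54 to 39.0. Neither the endothelial list (GNF5 adjusted p = 0.843) nor the leukocyte list (adjusted p = 0.195) was called by camera, while the fibroblast list had under 5 members past the minimum.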
